A study of Drosophila melanogaster with 3 samples.

How the data were processed

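Chromatin immunoprecipitation with an antibody against the MCM2-7 complex was followed by Illumina sequencing in Kc167 cells, per the labels' protocols. Of 3 samples, 2 were MCM immunoprecipitations from separately numbered chromatin extractions and 1 was an input from a further extraction. The labels do not say whether the extractions came from separate cultures, so SDs measure the spread between these samples, which may be technical. The p-values come from peaks, pairs or windows within these lists, and do not cover the spread between extractions. No values of the input were analysed here, so no background was measured in it. The 2 immunoprecipitations formed 1 group, taken from the sample titles, and the replicate numbers are those of the titles.

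Peaks were called with PeakSeq on FlyBase release 5.1, per the file headers and the caller named in the files. The aligner, the version and settings of the caller, its threshold and the use of the input are not given in the sources used here. There were 3 peak lists, 1 for each MCM replicate, with peaks called in each replicate alone, and 1 for the whole series. The deposited score of each peak is the authors' own and its unit is not stated in the file headers. It was used to describe, rank and filter peaks within a list, and to compare the order of shared peaks and the standing of sequences relative to the major arms between lists. The files hold no read counts, so depth is unknown, and no interval that needs it was computed. Starts and ends are given from 1, as in the files.

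Widths were computed as end minus start plus 1, and covered length after merging overlapping peaks. A peak was called shared when it overlapped a peak of the other replicate by at least 1 bp. Overlap was tested against 10000 circular shifts of the other list within each sequence, one-sided. Each sequence was taken to run from the first to the last peak of both replicates, because no sequence lengths of release 5.1 were used, so peaks per Mb are per Mb of that span. The scores of all overlapping pairs were compared by Spearman's rho, with a bootstrap of 1000 draws over pairs. Pairs on U, on the Het scaffolds and on chromosome 4 were each compared with pairs on the major arms by the difference of median log2 score ratios, with 100000 permutations of the pairs. The whole-series list was compared with the merged extents of overlapping replicate peaks. Peak counts on X and on the autosomal arms were tested against span by a chi-square test in each replicate, and by 100000 permutations of windows of 1 Mb, two-sided, and p is that of the replicate named or the larger one. Gaps between neighbouring peaks were compared with 1000 uniform placements on each arm, two-sided. Shares have exact Clopper-Pearson intervals at 95%. The threshold was 0.05, and adjusted p-values are by Benjamini and Hochberg. Values per replicate are summarised as the mean and SD of 2 lists. Shared percentages are the 2 directions of 1 overlap and are given without SD. The proximal block of an arm is the 2 Mb at its centromere end, from the known orientation of the Drosophila arms. Sharing outside the major arms was compared with 10000 draws of major-arm peaks matched in 20 bins of width or of score.

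The tests of overlap, gaps, X against the autosomal arms, score ratios and matched sharing were tested on simulated data; the chi-square tests and the ranks of blocks were not. For replicate overlap, unrelated lists of 10122 peaks gave an excess of -0.0122 percentage points with a randomization p of 0.529, and lists of 10112 peaks with 60.5% planted sharing gave 61.0%. For gaps between neighbours, 10122 evenly placed peaks gave a gap ratio of 0.991 with a randomization p of 0.388, and 8766 peaks in clusters of 5 gave 0.0924. For X against the autosomal arms, 10085 evenly placed peaks with no excess gave a ratio of 0.997 with a permutation p of 0.905. With a planted ratio of 1.3, 10660 peaks placed evenly within each arm gave 1.29. For score ratios, 66 pairs without a shift differed by -0.04 in median log2 ratio with a permutation p of 0.297, and a planted shift of -0.60 came out at -0.55. For matched sharing, 2000 narrow peaks whose sharing followed width alone differed from matched draws by 1.15 points with a randomization p of 0.883, and a planted deficit of -22.7 points came out at -22.3.

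Tests, alternatives, gene lists and the rule for named items were fixed before the data were examined. The gene table used here belongs to release 6 of the genome and the peaks to release 5.1, and positions were not carried from one release to the other. For that reason 4 planned results were left out, namely peaks near transcription start sites, peaks by annotation class, the 19 gene lists and the GC content of peaks, and no genes are named. The rule for named items was applied to regions alone, giving the 5 highest-scoring regions of the whole-series list that overlapped both replicates, the 3 windows of 100 kb with most shared regions and the 3 longest stretches without a peak. The widest regions, the longest runs of peaks and the longest peak-free stretches of the 6 arms were chosen after the data were seen. The same holds for comparing scores and sharing on U, the Het scaffolds and chromosome 4 with the major arms. The comparison of chromosome 4 with equally long blocks, and of U and the Het scaffolds with the arms in general, were also chosen then. So were the permutation of windows, the merging of peaks within 1 kb for arm counts and the proximal blocks. The search for unshared peaks within 1 kb of a peak of the other replicate was also added then.

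Alternatives were each replicate alone, the whole-series list, shared peaks only, the 50% of peaks with the higher score, covered length in place of peak number, 50% reciprocal overlap, extension of peaks by 500 bp, uniform placement, and merging of peaks within 1 kb. Computations used python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0, and plots used matplotlib 3.10.9.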

Results

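The MCM2-7 complex, the hexameric helicase that is loaded onto DNA at replication origins, was mapped by chromatin immunoprecipitation and sequencing in Kc167 cells, a female line derived from Drosophila melanogaster embryos and grown here as an asynchronous culture. The antibody was a mouse monoclonal raised against the yeast complex that binds the Walker B motif shared by the MCM subunits. The design holds 2 MCM immunoprecipitations, labelled as separate chromatin extractions and called replicate 1 and replicate 2 here, and 1 input sample, for which no values were analysed here. The measurements are lists of peaks called by the authors, with a score for each peak that is the authors' own and has no stated unit. Read numbers were not used here, so the sequencing depth behind each list is unknown. Positions are on FlyBase release 5.1, and no gene annotation of that release was used, so regions are named by chromosome, start and end.

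The first question was what each immunoprecipitation recovered. Replicate 1 held 10679 MCM peaks that covered 1973 kb, and replicate 2 held 8553 peaks that covered 1512 kb. The mean was 9616 ± 1503 peaks (SD, n = 2) and 1742 ± 326 kb (SD, n = 2), so replicate 1 had 1.25 times as many peaks as replicate 2. Peaks were short, with a median width of 133 bp in replicate 1 (interquartile range 71 to 240 bp, longest 2926 bp) and of 130 bp in replicate 2 (70 to 227 bp, longest 3025 bp). The median score was 2.56 in replicate 1 and 2.32 in replicate 2. All 3 lists covered the same 12 sequences, which were the arms 2L, 2R, 3L, 3R and X, chromosome 4, 5 scaffolds of mapped heterochromatin (2LHet, 2RHet, 3LHet, 3RHet and XHet) and U, the collection of sequence not placed on any chromosome. No Y sequence was among them. The shortest distance between neighbouring peaks was 200 bp in each replicate. At the lower end, 876 peaks of replicate 1 and 682 of replicate 2 were under 20 bp wide.

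The 5 highest-scoring MCM regions found in both replicates lay on U, 2R, 2L and X. The region on U from 7028168 to 7028260 led the whole-series list with a score of 12.1, against 10.7 in replicate 1 and 13.5 in replicate 2. It was followed by 2R from 3503034 to 3503085, with scores of 11.7 and 10.5 in replicates 1 and 2, and by 2L from 9158467 to 9158559, with 14.7 and 6.35. The fourth, on U from 3486469 to 3486586, scored 5.89 and 13.9, and the fifth, on X from 15217285 to 15217679, scored 11.2 and 8.51. These regions were 52 to 395 bp wide, with the one on X the widest. The 3 widest shared regions were others, namely 3R from 19151354 to 19154403 with 3050 bp, X from 2194460 to 2197448 with 2989 bp and 2L from 12010170 to 12012694 with 2525 bp. Their whole-series scores were 1.53, 1.64 and 4.17, respectively.

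The next question was whether the separate extractions placed MCM at the same positions. On the genome as a whole, 66.4% of the peaks of replicate 1 (7096 of 10679) overlapped a peak of replicate 2 by at least 1 bp, and 84.4% of the peaks of replicate 2 (7215 of 8553) overlapped a peak of replicate 1. When one list was shifted around each sequence 10000 times, the overlap averaged 2.40% for replicate 1 (95% of shifts between 2.09% and 2.72%) and 2.99% for replicate 2 (2.61% to 3.41%). The observed overlap was therefore 27.7 and 28.2 times the random value, with a one-sided p of 0.0001 in both directions, the smallest that 10000 shifts can give. Sharing was high on all 5 major arms. It ran from 65.4% on 2L to 69.3% on X for replicate 1 peaks, and from 86.1% on 2L to 88.0% on 3R for replicate 2 peaks. These are the 2 directions of 1 overlap between the same lists, so no spread between replicates can be given. It was lower outside them. On chromosome 4, the small and largely heterochromatic autosome, 45.0% of replicate 1 peaks and 56.5% of replicate 2 peaks were shared. On the Het scaffolds the shares were 26.2% and 35.0%, and on U they were 47.1% and 26.5%. The exact binomial 95% intervals of the Het shares, 20.1% to 33.1% and 27.1% to 43.6%, lay below those of the major arms, 66.7% to 68.5% and 86.4% to 87.9%. These intervals cover counting error only.

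Shared MCM peaks were wider than the others. In replicate 1 the median width was 190 bp for shared peaks and 59 bp for the rest, and in replicate 2 it was 152 bp and 39 bp. When the peaks of replicate 1 were ranked by width into 10 groups of about equal size, 98.4% of the widest group, from 402 bp upward, were shared, against 25.1% of the second narrowest, of 27 to 57 bp. In replicate 2, 97.5% of the widest group, from 378 bp upward, were shared, against 58.6% of the second narrowest, of 26 to 56 bp. Scores separated shared from unshared peaks less, with medians of 2.76 and 2.17 in replicate 1 and of 2.35 and 2.16 in replicate 2. Peaks of the major arms without a partner often lay near some peak of the other replicate. Of 3329 such peaks in replicate 1, 42.1% were within 1 kb of a replicate 2 peak, against 12.1% after random shifts, and of 1042 in replicate 2, 63.0% were within 1 kb of a replicate 1 peak, against 14.8%. The one-sided p was 0.0001 in both cases, the smallest that 10000 shifts can give. Shifts also break the clustering that both lists share. The result therefore places unshared peaks in the same zones, but does not match them with single peaks. Within their own list, 49.1% of replicate 1 peaks and 44.3% of replicate 2 peaks on the arms and chromosome 4 had a neighbour within 1 kb.

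MCM regions that scored high in one extraction also scored high in the other. Across 7282 overlapping pairs, Spearman's rho between the scores was 0.858 (bootstrap 95% interval 0.851 to 0.865). Peaks are not independent replicates, and this value describes these lists only. Within each list, the shared peaks of chromosome 4 scored above those of the major arms, by a ratio of medians of 1.19 in replicate 1 and 1.17 in replicate 2. Those of the Het scaffolds scored below them, with ratios of 0.764 and 0.750. The shared peaks of U changed sides, since their median score was 0.688 times that of the major arms in replicate 1 and 1.17 times in replicate 2. Accordingly, 93.9% of the 66 pairs on U had the higher score in replicate 2, against 13.5% of the 7131 pairs on the major arms. The median log2 ratio of replicate 1 to replicate 2 scores was -0.52 on U and 0.23 on the major arms, and a permutation of the pairs between these sequences gave a two-sided p of 1e-05, the smallest that 100000 permutations can give. The ratios on chromosome 4, with a median of 0.26 over 36 pairs, and on the Het scaffolds, with 0.20 over 49 pairs, were not distinguishable from those of the major arms (permutation p = 0.408 and p = 0.491).

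**Figure D1:**
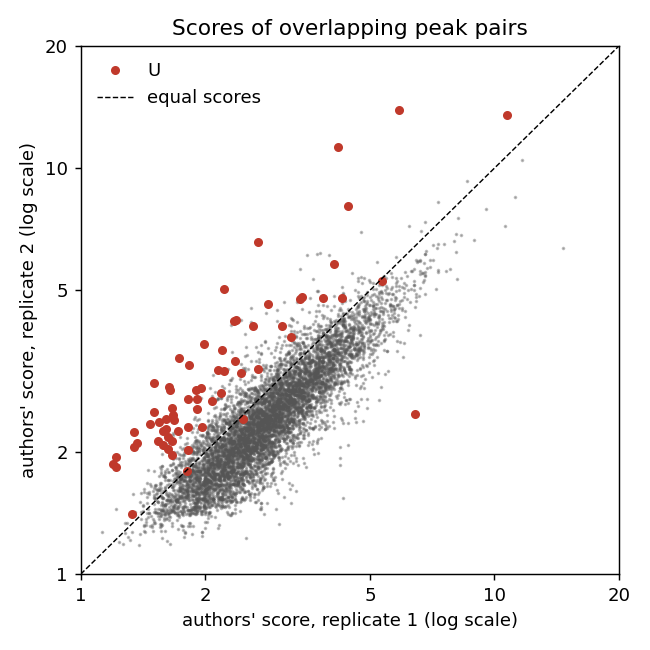
Scores of overlapping MCM peak pairs, with the authors' score in replicate 1 on the x axis and in replicate 2 on the y axis, both on log scales and without unit; each point is a pair, red points lie on U, grey points on all other sequences, and the dashed line marks equal scores. Red points lie mostly above the line (93.9% of 66 pairs), and grey points mostly below it.

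The whole-series list held the MCM regions that both extractions had in common. It contained 7029 regions with a median width of 208 bp and a total of 1876 kb, and 100% of them overlapped peaks of both replicates. Merging the peaks of the replicates wherever they overlapped gave 11950 regions, of which 7029 held peaks of both, 3583 held replicate 1 peaks only and 1338 held replicate 2 peaks only. All 7029 shared regions had the same start and end as a region of the whole-series list, and 6962 of its scores equalled the mean of the scores of the peaks within, at a tolerance of 1e-05. The other 67 differed by at most 0.187. A stricter rule, that each replicate cover at least 50% of the region, was met by 77.8% of the regions. The regions of this list can thus be derived from the 2 replicate lists, and it was not counted as an independent measurement.

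Among the chromosome arms, MCM peaks were densest on X. X carried 86.7 ± 12.9 peaks per Mb (SD, n = 2), against 75.3 ± 12.9 (SD, n = 2) on the 4 large autosomal arms together, a ratio of 1.15 ± 0.0272 (SD, n = 2) that was above 1 in both replicates (1.13 and 1.17). Among the autosomal arms, 2R was highest with 82.6 ± 14.1 peaks per Mb (SD, n = 2) and 2L lowest with 68.2 ± 12.4 (SD, n = 2), while 3L had 75.2 ± 12.6 and 3R had 75.8 ± 12.7. Chromosome 4 had 58.2 ± 10.4 peaks per Mb (SD, n = 2). The 3 longer scaffolds of mapped heterochromatin were sparse, with 15.3 ± 3.08 on 2RHet, 22.1 ± 5.62 on 3LHet and 23.1 ± 5.18 on 3RHet (SD, n = 2 each), and U had 19.3 ± 7.79 (SD, n = 2). U was the only one of these sequences with more peaks per Mb in replicate 2 (24.8) than in replicate 1 (13.7), and its share of all peaks was 2.86% (exact binomial 95% interval 2.52% to 3.24%) in replicate 2 and 1.27% (1.07% to 1.50%) in replicate 1. The short scaffold XHet was dense, with 96.6 ± 9.10 peaks per Mb (SD, n = 2), above every arm, but this rests on 8 and 7 peaks over a span of 0.0777 Mb. On 2LHet, 2 peaks were called in each replicate.

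**Figure D2:**
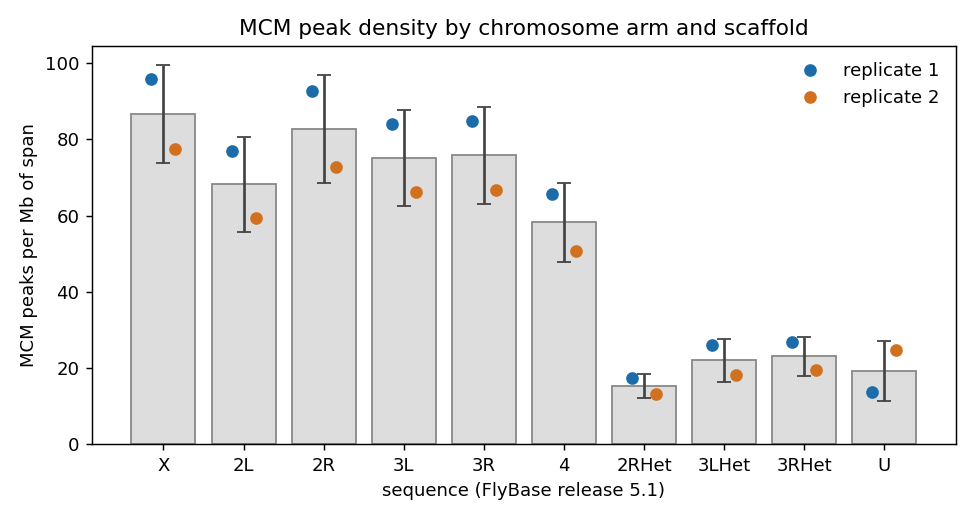
MCM peaks per Mb (y axis) on each arm, on chromosome 4, on the 3 longer Het scaffolds and on U (x axis); bars show the mean of the 2 replicates, error bars the SD, and points each replicate. X is the highest at 86.7 and 2RHet the lowest at 15.3, and only on U does replicate 2 lie above replicate 1.

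The difference between X and the autosomal arms was past the threshold in both replicates. A chi-square test of peak counts against arm length gave p = 4.03e-09 in replicate 2 and p = 2.21e-07 in replicate 1, but it treats peaks as independent, and the variance of counts over 1 Mb windows was 6.11 and 5.43 times their mean. A two-sided permutation of 22 windows of X and 94 autosomal windows, added after the data were seen, gave p = 0.028 in replicate 1 and p = 0.0104 in replicate 2. It treats windows as exchangeable, although those along an arm are not independent and X is a single chromosome. The autosomal arms also differed from each other, with 68.2 peaks per Mb on 2L and 82.6 on 2R. The simulated lists for this test held evenly placed peaks, without the excess variance seen here. Against single arms, X exceeded 2L with a ratio of 1.27 (permutation p = 0.00927, Benjamini-Hochberg adjusted p = 0.0371 over 4 comparisons, higher in both replicates). The ratios to 3R (1.16, adjusted permutation p = 0.0729), 3L (1.15, adjusted permutation p = 0.118) and 2R (1.06, adjusted permutation p = 0.521) did not pass. Once peaks within 1 kb of each other were merged, the ratio of X to the autosomal arms was 1.09 and no longer passed (permutation p = 0.276). In covered length it was 1.25 (permutation p = 0.00312).

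Chromosome 4 carried 0.772 ± 0.00600 times (SD, n = 2) as many peaks per Mb as the large autosomal arms, with 80 peaks in replicate 1 and 62 in replicate 2. Its peaks were narrow, with a median width of 73.0 ± 17.7 bp (SD, n = 2) against 133 ± 1.41 bp on the large autosomal arms, and its scores were higher, with a median of 2.83 ± 0.245 against 2.42 ± 0.177 (SD, n = 2 each). The chi-square test, which treats peaks as independent, gave p = 0.0379 in replicate 2 and p = 0.0239 in replicate 1. The deficit was larger in the whole-series list (ratio 0.510) and in covered length (0.437), but among the 50% of peaks with the higher score the ratio was 1.08 (chi-square p = 0.75), and with peaks within 1 kb merged it was 0.880 and no longer passed (chi-square p = 0.457). Blocks of the major arms as long as chromosome 4 varied widely, from 9 to 164 peaks around a median of 108 in replicate 1, and 15 of 95 such blocks held fewer peaks than chromosome 4 (13 of 95 in replicate 2), so its count lay within the range of the arms.

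MCM peaks thinned out toward the centromere on 4 of the 5 major arms. The 2 Mb nearest the centromere of 3L, from 22533862 to 24533861, held 23.3 ± 6.72 peaks per Mb (SD, n = 2), against 79.8 ± 13.1 on the rest of the arm, a ratio of 0.288 ± 0.0367 (SD, n = 2). On 2R, from 18416 to 2018415, the ratio was 0.296 ± 0.0384 (SD, n = 2). It was 0.529 ± 0.0496 on X, from 20415367 to 22415366, and 0.674 ± 0.0785 on 2L, from 20961202 to 22961201 (SD, n = 2 each). The proximal block of 3R, from 174 to 2000173, differed from these with a ratio of 1.02 ± 0.0185 (SD, n = 2). On 2R, 3L and X, no other 2 Mb block of the arm (9, 11 and 10 blocks, respectively) held fewer peaks in either replicate. On 2L, 1 of 10 other blocks held fewer in replicate 1 and none in replicate 2. On 3R, 6 of 12 other blocks held fewer in replicate 1 and 8 of 12 in replicate 2. This comparison was chosen after the data were seen and has no test beyond these ranks. No read counts or input values were used, so less MCM cannot be told apart from fewer positions at which a peak could be called. With a block of 1 Mb the ratio was 0.0733 on 3L and 0.298 on X, and among the 50% of peaks with the higher score it was 0.153 on 2R, 0.409 on 2L and 0.894 on 3R.

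**Figure D3:**
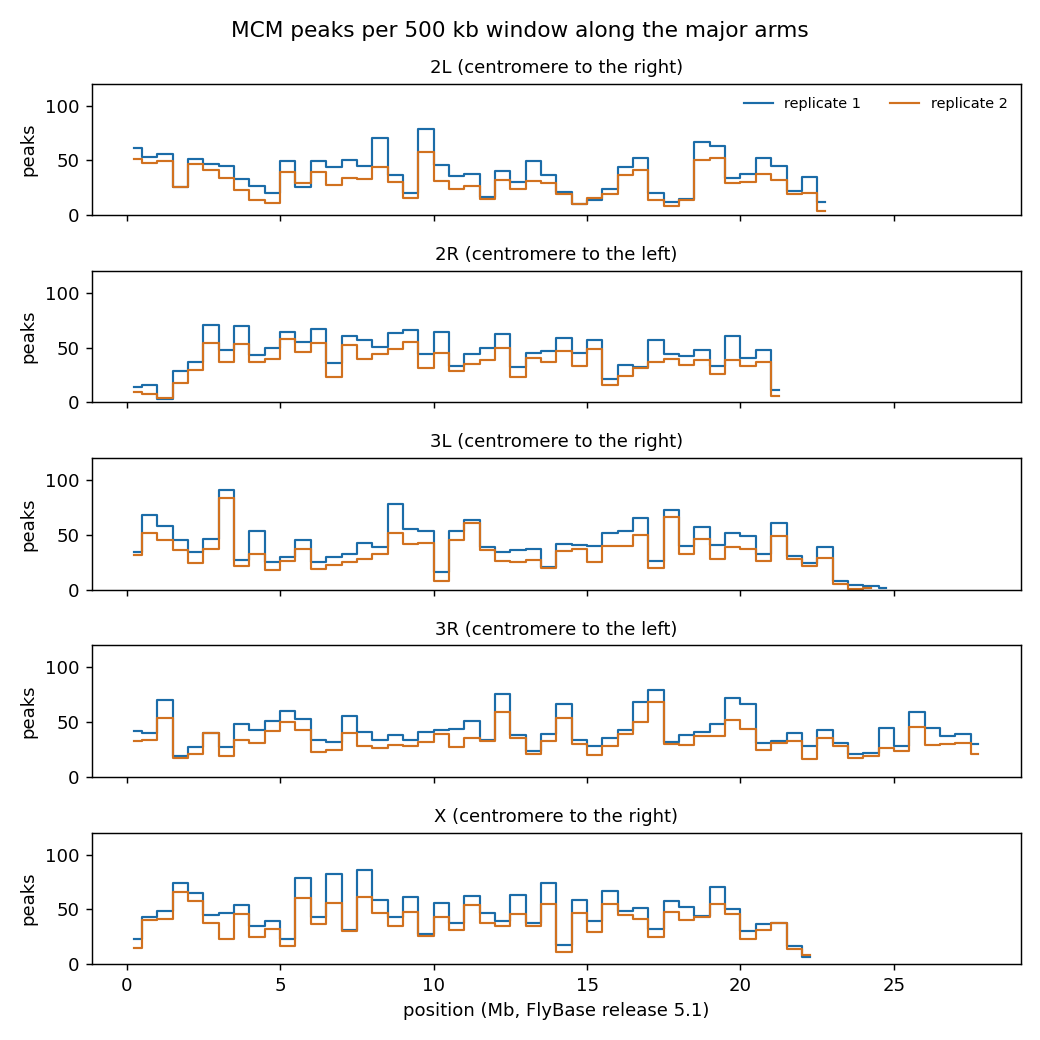
MCM peaks per 500 kb window (y axis) along the 5 major arms (x axis, position in Mb on FlyBase release 5.1), with blue lines for replicate 1 and orange lines for replicate 2; the title of each panel gives the side on which the centromere lies. Counts drop at the centromere end of 2R and 3L, where the ratios of the last 2 Mb to the rest were 0.296 and 0.288, and not at that of 3R.

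Along the arms, MCM peaks lay in clusters. The densest stretch of 100 kb was on 3R from 12000001 to 12100000, with 32 regions found in both replicates. It was followed by 3R from 17400001 to 17500000 with 29 shared regions and 2L from 1100001 to 1200000 with 28. The longest run of peaks with gaps of at most 5 kb held 31 peaks in replicate 1, on 3L from 8660910 to 8701404, and 21 peaks in replicate 2, on 2L from 1142727 to 1186507. At the other extreme, the 3 longest stretches without a peak in either replicate were on U, the first of 706 kb from 4899023 to 5604566, the second of 689 kb from 7969956 to 8659019 and the third of 573 kb from 9192259 to 9764867. Because U collects sequence not placed on any chromosome, these stretches need not be contiguous in the genome. On the arms and chromosome 4, the longest were on 3L from 24168815 to 24526681 (358 kb), on 3L from 23331259 to 23659678 (328 kb) and on 2L from 16888975 to 17196748 (308 kb). There were 143 peak-free stretches of over 100 kb on these 6 chromosome arms, while the median free stretch was 2.92 kb.

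**Figure D4:**
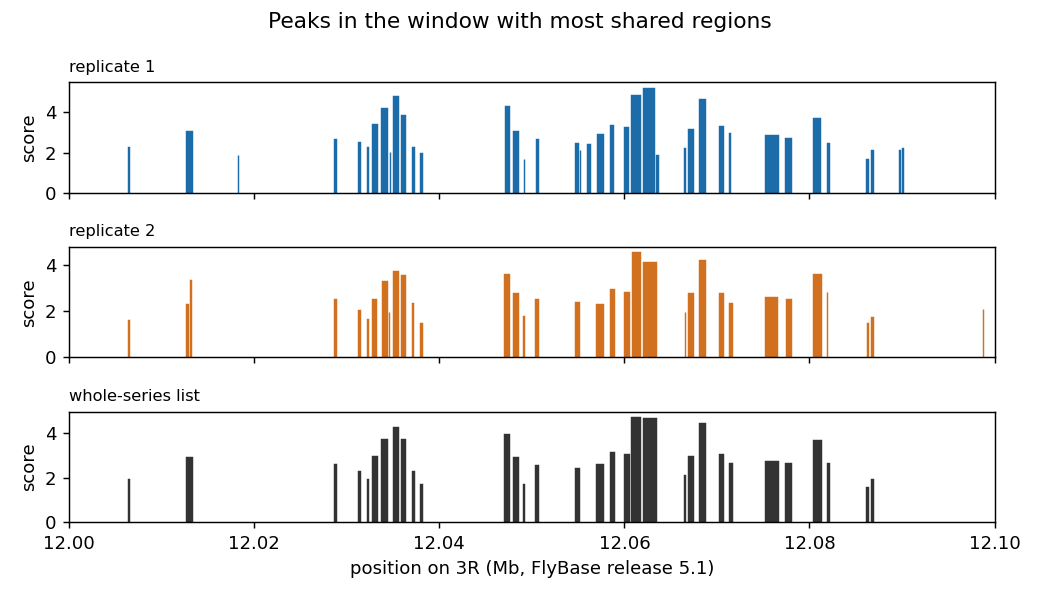
MCM peaks on 3R from 12000001 to 12100000 (x axis, position in Mb on FlyBase release 5.1), with the authors' score on the y axis; each bar spans a peak to scale, in replicate 1 (top, blue), replicate 2 (middle, orange) and the whole-series list (bottom, black). The window holds 39 peaks of replicate 1, 35 of replicate 2 and 32 shared regions.

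The clustering exceeded that of evenly placed peaks in both replicates. The median gap between neighbours on the 6 arms was 3390 bp in replicate 1 and 4396 bp in replicate 2, and the same number of peaks placed uniformly gave 7803 bp and 9887 bp. The ratio of observed to even placement was 0.439 ± 0.00725 (SD, n = 2). The coefficient of variation of the gaps was 1.95 ± 0.0638 times (SD, n = 2) that of even placement. Both measures had a two-sided randomization p of 0.002, the smallest that 1000 placements can give. With peaks within 1 kb merged, the gap ratio was 0.626 and the ratio of variation 1.58, both nearer to even placement. Part of the clustering thus lies in neighbouring calls. Uniform placement used the whole span of each arm, and positions at which no peak could be called were not left out. In replicate 1, 49.1% of the peaks had a neighbour within 1 kb and 89.2% within 10 kb, and in replicate 2 these shares were 44.3% and 86.2%. Runs of 5 or more peaks with gaps of at most 5 kb numbered 515 in replicate 1, where they held 36.3% of the peaks on these arms, and 322 in replicate 2, where they held 26.7%. Counts of peaks per 100 kb were correlated between the replicates, with Pearson's r of 0.946 and Spearman's rho of 0.950 across 1184 windows. Peaks shared by the replicates enter both counts, and for unshared peaks alone Pearson's r was 0.475 and Spearman's rho 0.472. Of these windows, 68 were empty in both. Windows along an arm are not independent replicates.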

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

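Of 81 alternatives over 15 results, 61 kept the direction and the side of the threshold or moved by less than the spread between replicates, 17 moved by more, 2 lost their call and 1 reversed a called result. For results without a test, leaving out 1 of 2 replicates always moves the mean by less than their SD, so these settings could only count as kept. The percentage shared on the Het scaffolds, chromosome 4 and U minus that on the major arms counted so at -53.8 and -30.6 points. These 2 values are the directions of 1 overlap, so their distance is not a spread between replicates. The whole-series list and the shared peaks rest on the same regions and are not separate checks. Merging peaks within 1 kb for arm counts, proximal blocks and window permutations were added after the data were seen. So were the settings for scores on U and for sharing on the Het scaffolds, chromosome 4 and U. The other settings for peaks per Mb on chromosome 4 were fixed beforehand. The excess of replicate overlap over random placement and the clustering of peaks passed under each alternative run. Gap ratios ran from 0.434 in replicate 1 alone to 0.626 with peaks within 1 kb merged. With 50% reciprocal overlap, rho between scores rose to 0.896, and with the rule that 50% of a region be covered, 77.8% of the whole-series regions overlapped both replicates. The excess of X lost its call when peaks within 1 kb were merged (1.09, chi-square p = 0.0507). It was 1.13 and 1.17 with 1 replicate left out and 1.09 to 1.29 over all alternatives. The deficit on chromosome 4 rests on a chi-square test that treats peaks as independent, and its count lay within the range of equally long blocks of the arms. It lost its call with the same merging (0.880, chi-square p = 0.457) and moved to 0.437 in covered length. It reversed to 1.08 among the 50% of peaks with the higher score, a setting that keeps fewer peaks. Chromosome 4 peaks were narrower than those of the large autosomal arms (mean of medians 73.0 against 133 bp), which lowers covered length. They also scored higher (2.83 against 2.42), so a larger share of them passed the score cut. The causes of these widths and scores, and of the change on merging, were not tested. The remaining values that moved belong to the ratios of proximal blocks, none of which has a test. The lowest were 0.409 on 2L and 0.153 on 2R, among the higher-scoring peaks, and 0.0733 on 3L and 0.298 on X, with a block of 1 Mb. The ratio on 3R went from 1.02 to below 1 in both of these settings (0.894 and 0.985). Some moves weakened the thinning. On X the ratio rose from 0.529 to 0.586 in covered length, 0.611 among shared peaks and 0.626 in the whole-series list. On 3L it rose from 0.288 to 0.335 in covered length. Results near start sites, by annotation class, for gene lists and for GC content, and their alternatives, were not run, because no annotation or genome of the files' release was used. No paired analysis was possible because there is 1 group with peak lists. Unknown depth keeps differences in peak number between the replicates from being read as differences in binding.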

Other observations

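The tests of the U scores and of matched sharing, and the use of covered length as a test of split zones on X, were chosen after the results were seen, although covered length itself was fixed beforehand. The merging of peaks on X, the removal of proximal blocks and the permutation of windows were added after the data were seen. Some single peaks scored above every region of the whole-series list. In replicate 1, 8 peaks scored above its highest value of 12.1, and 5 of them lay on U. The highest, at 325, was 40 bp wide and lay on U from 6047256 to 6047295. In replicate 2, 7 peaks passed that score and 6 of them lay on U, led by a 46 bp peak from 7969910 to 7969955 with a score of 199. Of these peaks, 1 in replicate 1 and 2 in replicate 2 overlapped a peak of the other replicate.

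MCM peaks on U stood lower than those on the arms in replicate 1 and higher in replicate 2, although they were shared peaks at overlapping positions. A difference between the extractions in heterochromatic DNA at large was considered as a cause of this shift. The median log2 ratio over the 49 shared pairs on the Het scaffolds was 0.20, close to that of the arms, so their scores did not show the shift. This cannot decide on the cause, because a scaling of the score by sequence could hide such a difference there. Whether the extractions differed in the amount of that DNA was not measured. The ratios also spread more widely on U, with an SD of 0.38 across pairs against 0.22 on the major arms. A scaling of the score by sequence and a different amount of U DNA in the libraries both stay open, since neither was tested without read counts, and no biological explanation was tested.

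Peaks on the Het scaffolds, U and chromosome 4 were shared less often than those on the major arms. The values of replicates 1 and 2 are the 2 directions of 1 overlap, and not separate measurements of sharing. Narrow peaks were shared less often in both replicates, but on the Het scaffolds the shared percentage lay below that of major-arm peaks of matched width by a mean difference of -28.8 points (-18.6 in replicate 1 and -39.0 in replicate 2) and below that of matched score by -39.8 (-29.5 and -50.1). On U the mean differences were -33.0 at matched width (-13.9 and -52.2) and -37.6 at matched score (-13.4 and -61.8), far larger in replicate 2. However, U held 136 peaks in replicate 1 and 245 in replicate 2, so many replicate 2 peaks there had no possible partner. On the major arms replicate 1 held more peaks, 10276 against 8109. The matched draws do not allow for this, so the size of the difference in replicate 2 cannot be read as poorer agreement alone. On chromosome 4 the difference at matched score was -30.4, whereas at matched width it was -10.8 as a mean of 0.485 in replicate 1 and -22.1 in replicate 2, so narrow peaks cannot be told apart from a property of the chromosome there. Reads that map to repeated sequence may place peaks differently in each library, which was not tested, and neither was any biological explanation.

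The excess of MCM peaks on X has several technical candidates. Sparse blocks near the centromeres do not account for it, since the ratio to the autosomal arms without them was 1.16 (larger permutation p = 0.0104). Among the higher-scoring peaks the ratio was 1.29 (permutation p = 0.00084), so the excess was not confined to low-scoring peaks. This counts against extra weak calls on X only if scores compare between X and the autosomal arms, which is not known. The threshold of the caller is not known to be set on this score, so extra calls near that threshold stay open. Splitting of zones into more calls stays open for the number of peaks, because the ratio after merging was 1.09 (permutation p = 0.276), but it could not account for the covered length, with a ratio of 1.25 (permutation p = 0.00312). A difference in DNA copy number or depth between X and autosomes also stays open, since no read counts were used and the median score on X was 1.05 times that on the autosomal arms. No group in the design bears on a biological explanation, and none was tested.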
